A study of Fucus vesiculosus with 50 samples.

How the data were processed

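RNA from 50 pieces of Fucus vesiculosus (5 grazed and 5 control pieces at each of 5 sampling days) was measured on 50 custom Agilent arrays, 1 per piece. Per the labels' protocols, pieces were kept in aquaria of 25 litres at 18.1 °C with 12 hours of light, RNA was extracted with a CTAB buffer, and 200 ng were amplified and labelled with an Agilent low-input kit to which random hexamers with a T7 promoter were added. Per the labels, the sample carried Cy3 and a pool of RNA from 5 pieces of day 0 carried Cy5 on all arrays, without dye swaps. The labels name the reference of grazed arrays and of control arrays differently, while the design text speaks of 1 pool. The descriptions of the samples titled day 21 and day 24 state 18 and 21 days, and those of grazed samples of days 15, 21 and 24 name I. baltica as the grazer. Groups were taken from the titles and group labels, which say days 21 and 24, and from the treatment protocol, which names Littorina obtusata only.

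Per the file headers, the scans were read out with Agilent Feature Extraction 10.7.3.1. The deposited array files hold the intensity of each spot and of its local background as medians of pixels, not processed further per the file headers. They also hold a processed intensity, which per the file headers was corrected for background and spatial trend and normalised between dyes, and its log10 ratio of Cy5 to Cy3. Flags for background, saturation and outlying spots are 0 or 1 in the deposited files. The authors' deposited table gives ratios as fold changes per day for a selected list of probes, with the fold of day 12 signed and the others unsigned beside a direction. How those probes were chosen was not stated in the labels used here.

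Log ratios were computed with limma 3.58.1 in R 4.3.3. Median signals were used because the files hold no mean signals, which the plan had named. Background was corrected with normexp (offset 50), followed by loess within each array with control spots and outlying spots at weight 0, without scaling between arrays, and the ratio was expressed as log2 of Cy3 over Cy5. Each probe has 1 spot. In all 944 outlying spots were left out.

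The first fit with these settings contained an error of processing, found only after its results had been seen. On grazed day 3 replicate 3 a bright patch raised the local background in Cy3 to 710490 at its highest, against an array median of 21, and the normexp parameters of the whole array diverged. The log of the normexp spread was 9.04 in Cy3 and 7.17 in Cy5 on that array, and the median absolute log2 ratio was 0.0096, against 0.18 to 0.51 on the other arrays. On control day 3 replicate 3 the log of the spread in Cy5 was 4.5. On all arrays, spots with a local background over 3 times the array median in either channel, 71 spots on 9 arrays, were therefore treated apart. They were given the median background of their array for the correction and weight 0 in the loess, and their ratios were left out afterwards. It was decided before the repaired results were seen that they would replace the first ones. After the repair the median absolute log2 ratio of grazed day 3 replicate 3 was 0.24. The first fit is kept as an alternative, and its counts are given with the other alternatives.

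Probes were kept if they were well above background in Cy3 on at least 4 of the 5 arrays of at least 1 group, which left 36998 of 40983. One model with a mean for each of the 10 groups was fitted to all 50 arrays with limma's lmFit and eBayes. The contrasts were grazed minus control on each day, their mean over the 5 days, the change of the contrast between days (F test), the control groups between days (F test), and each arm against day 0. P-values were adjusted after Benjamini and Hochberg with a threshold of 0.05, and the tests of single contrasts covered both directions. The median SE was 0.215 for a daily difference and 0.0963 for the mean over the 5 days.

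The procedure was tested on simulated data made from shuffled residuals of these arrays with 200 changed probes in each of 5 draws. At day 15 it found 59.2% of changes of 1 and 94% of changes of 2 on the log2 scale. For the mean over 5 days it found 65.2% of changes of 0.5 and 92.8% of changes of 1, with a median of 2 and at most 363 unchanged probes called per draw.

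The rule for named probes was fixed before the data were examined. It asked for annotated genes, or, where the files pair no probe with a name, for at most 2 probes that rose and 2 that fell per comparison. The files give no names, so this part of the rule applied, and the planned gene lists, marker lists and set tests could not be run.

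The median of detected probes in Cy3 was 77.7% per array, the median Cy3 signal was 3.2 to 21.3 times the local background, and no kept probe was saturated in Cy3 on any array. Arrays came from 14 slides and were scanned on 5 days. Replicate numbers were checked as pairs by the correlation of deviations from the group means. Every pair of day 15 exceeded 0.1 (0.14 to 0.64), so the numbers were taken to pair the pieces of that day. At the other days at least 1 pair did not, and the numbers were not taken as pairs there, although 18 of 25 pairs in all exceeded 0.1: the correlations were 0.07 to 0.72 at day 3, -0.1 to 0.68 at day 12, -0.03 to 0.52 at day 21 and -0.06 to 0.65 at day 24. Pairing on those days stays possible, and the main fit used no pairs on any day. The 2 most alike arrays, grazed day 15 replicates 2 and 5, had a correlation of log ratios of 0.918 across probes and differed by up to 3.42, so they were not copies.

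The settings varied from the start were Agilent's own log ratio, the sample channel alone, no background correction, an offset of 10, median centring, scaling between arrays, no filter and a strict filter, slide as a block, fits within single slides, the replicate number as a block, array weights, separate fits per day and the omission of each array. Settings added after seeing the data were scan day as a block, fits within single scan days, blocks of day and number, omission of the 7 arrays with over 89% of probes detected, and the first fit with the bright spots. Figures were drawn with matplotlib 3.10.9.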

Results

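Transcript levels were measured in apical tips of the brown seaweed Fucus vesiculosus that were grazed by the periwinkle Littorina obtusata, a marine snail, or left ungrazed. Pieces were sampled after 3, 12, 15, 21 and 24 days, with 5 biological replicates of each arm on each day, which makes 10 groups and 50 arrays. Each 2-colour array set 1 sample (Cy3) against a pool of RNA from 5 pieces taken at day 0 (Cy5), so that 0 on the log2 scale is the level of the pool. The array carried 40983 probes, of which 36998 were kept. The share of probes well above background in Cy3 was between 69.8% and 97.8% per array, with a median of 77.7%. It was highest in the grazed pieces of day 24, at 90.9% ± 6.6 (SD, n = 5), beside 85% ± 9.3 (SD, n = 5) in the controls of that day. The number of arrays limits the precision. The deposited files pair no probe with a gene, so transcripts are named by their probe identifiers.

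The first comparison asked which transcripts differ between grazed and ungrazed pieces over the whole experiment. Averaged over the 5 days, 24 probes passed the threshold of limma's test, 23 lower and 1 higher in grazed pieces. The differences of the 23 lower probes lay between -1.87 and -0.29 on the log2 scale, with a median of -1.32. In control pieces the median of these probes per array was 0.17 ± 0.63 (SD, 25 arrays) on the log2 scale over day 0, and in grazed pieces it was -0.84 ± 0.36 (SD, 25 arrays). It lay below the mean of the same day's controls on 24 of 25 grazed arrays, the arrays on which these probes were selected, so this tally is no separate evidence. An omission of the 7 arrays with over 89% of probes detected was chosen after seeing the data. It left grazed day 24 replicate 3 as the only grazed array of its day. The probes called in that fit are therefore not set against the 24.

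Probe CUST_42366_PI408257168 was lower in grazed pieces by 3.65-fold, a log2 difference of -1.87 (SE 0.34, 95% confidence interval -2.56 to -1.17, limma adjusted p = 0.022). Its level was 0.44 ± 1.59 (SD, 25 arrays) in control and -1.43 ± 1.04 (SD, 25 arrays) in grazed pieces, and 24 of 25 grazed arrays, on which the probe was selected, lay below the control mean of their day. Probe CUST_42367_PI408257168, whose number follows it, was lower by 3.57-fold, a log2 difference of -1.84 (SE 0.35, limma adjusted p = 0.022). The correlation of these probes' deviations from the group means was 1, so they are not separate evidence. Both calls were lost with scan day as a block (limma adjusted p = 0.115 and 0.126, differences -2.278 and -2.272). Probe CUST_47029_PI408257168 was higher in grazed pieces by 1.64-fold, a log2 difference of 0.71 (SE 0.14, 95% confidence interval 0.42 to 1, limma adjusted p = 0.031). Its level was -0.86 ± 0.64 (SD, 25 arrays) in control and -0.15 ± 0.67 (SD, 25 arrays) in grazed pieces, and 21 of 25 grazed arrays, on which it was selected too, lay above the control mean of their day. This call was lost in 21 of 50 omissions of 1 array, with slide as a random block (limma adjusted p = 0.054, difference 0.7081), without the 7 arrays (0.0615, difference 0.7696) and with scan day as a block (1, difference 0.5844).

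**Figure D1:**
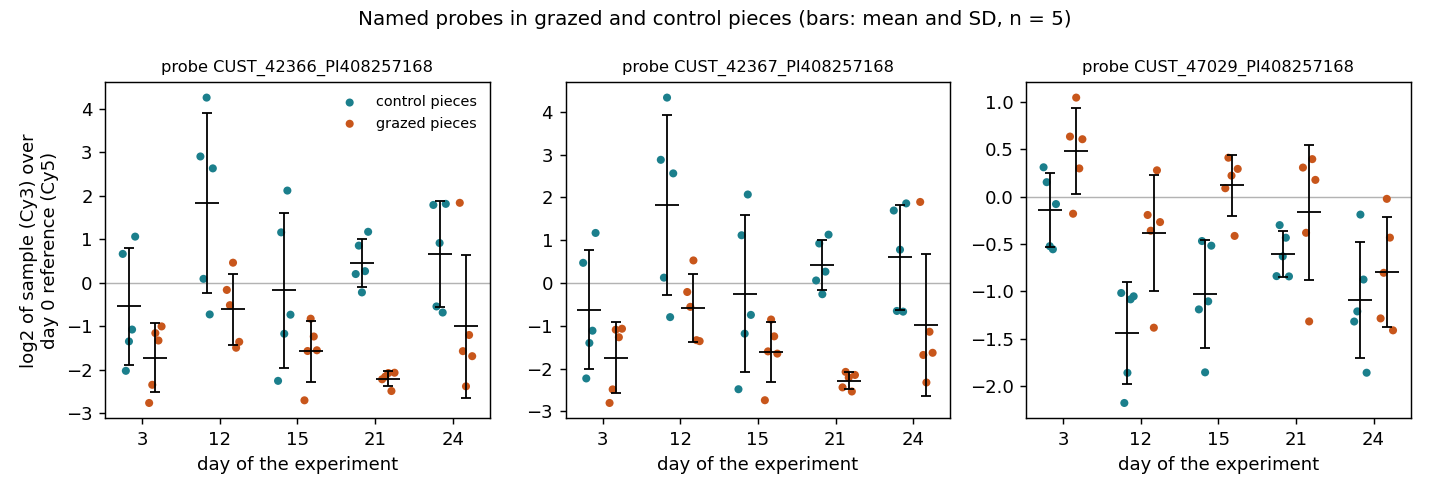
Log2 ratio of sample (Cy3) to day 0 reference (Cy5) for the named probes, by day of the experiment (x axis), with 1 point per array, control pieces in teal and grazed pieces in orange, and black bars for the mean and SD of 5 arrays. CUST_42366_PI408257168 had its lowest group mean in grazed pieces of day 21, at -2.21, and CUST_47029_PI408257168 its lowest in control pieces of day 12, at -1.44.

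The median difference of the 23 lower probes was -1.12 at day 3, -1.45 at day 12, -1.37 at day 15, -1.47 at day 21 and -1 at day 24. Of the 24 probes, 21 had the sign of their mean on all 5 days. With 1 array left out, the count was 15 to 45. With scan day as a fixed block, chosen after seeing the data, 0 of the 24 probes passed and 6 others did, all higher in grazed pieces. In that limma fit the median adjusted p of the 24 probes was 0.4, the median SE rose from 0.25 to 0.34, and the median of the lower probes was -1.49. Its day 21 part runs through grazed day 24 replicate 2 alone, because no scan day held both arms of day 21.

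**Figure D2:**
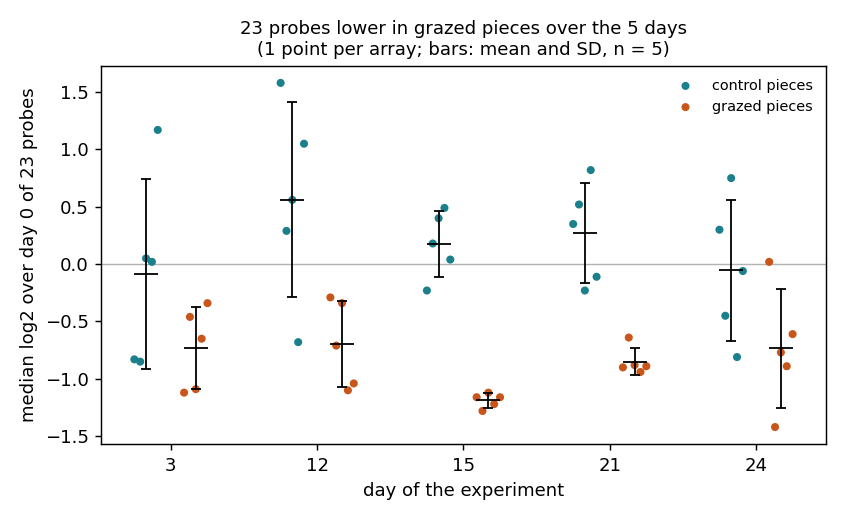
Median log2 ratio to the day 0 reference of the 23 probes lower in grazed pieces (y axis) by day of the experiment (x axis), with 1 point per array, control pieces in teal and grazed pieces in orange, and black bars for the mean and SD of 5 arrays. The probes were selected for this difference, and the 25 grazed arrays lie between -1.42 and 0.02 against -0.85 to 1.58 for the 25 control arrays.

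The second comparison set grazed against control pieces on each day. No single probe passed the threshold on any day: limma called 0 of 36998 probes at days 3, 12, 15, 21 and 24. This changed with the model: with slide as a fixed block limma called 54 probes at day 3, and with array weights 269 at day 12 and 57 at day 15. Only slide 2 held both arms of day 3, so the 54 rest on its 2 arrays of each arm. With slide as a fixed block, probes passed at days 21 and 24 too. Only 1 slide held both arms of day 24, with 1 grazed array, and no slide held both arms of day 21. Both estimates run through that array, grazed day 24 replicate 1, so their counts decide nothing and are given only with the other settings. Its median correlation with the other arrays in Cy3 was 0.783. With median centring it called 573 at day 21. At an unadjusted p under 0.05 there were 1659 probes at day 3, 1508 at day 12, 1315 at day 15, 2268 at day 21 and 1219 at day 24, where 1850 would be expected by chance. At day 21, 1455 of these were lower and 813 higher in grazed pieces. At day 3, 1208 were lower and 451 higher. For CUST_42366_PI408257168 the daily differences were -1.18, -2.45, -1.4, -2.66 and -1.66 in the order of the days (SE 0.77), and none passed after adjustment. The 95% confidence interval of the daily difference lay within 2-fold either way for 79.7% to 83.2% of probes.

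At day 15 the replicate numbers were taken to pair the pieces, and on the other days pairing stays possible. With day and number as a block on all days, chosen after seeing the data, limma called 1 probe (fixed block) or 18 probes (random block) at day 15. Within single scan days, also chosen after seeing the data, limma called 0 probes at days 3, 12 and 24 (730, 1273 and 388 at an unadjusted p under 0.05) and 1 at day 15, and no scan day held both arms of day 21. Fits within single slides were planned. Slides 2 and 7 held 2 arrays of each arm of days 3 and 15, and limma called 0 probes within each (2158 and 2157 at an unadjusted p under 0.05). The arrays of slide 2 are those behind the day 3 estimate with slide as a fixed block, where the spread came from all arrays.

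Whether the difference between grazed and control pieces changed with the day was tested for every probe by limma's F test of the 4 differences between daily contrasts. It called 0 probes, with 1235 at an unadjusted p under 0.05. Of the alternatives chosen after seeing the data, scan day as a block gave 6 probes, with day 21 estimated through grazed day 24 replicate 2 alone. The count without the 7 arrays is not used, because grazed day 24 replicate 3 is then the only array of its group. For the named probes CUST_42366_PI408257168, CUST_42367_PI408257168 and CUST_47029_PI408257168 the adjusted p of this test was 1. In simulated data the test found 10.4% of changes of 0.5 on the log2 scale, 36.8% of changes of 1, 57.6% of changes of 1.5 and 84.8% of changes of 2.

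Control pieces alone were compared across the 5 days, to see how ungrazed pieces drifted in the aquaria. Limma's F test called 48 probes, and 4749 at an unadjusted p under 0.05. The count was 1846 with the sample channel alone, 177 with Agilent's log ratio, 16 with scaling between arrays and 10 with a strict filter, and 1 other grouping of the control arrays gave 819. For 39 of the 48 probes, day 3 was the day farthest from the others. In the mean of the later control days 38 probes were lower than at day 3, with medians against day 3 of -1.47 at day 12, -3 at day 15, -2.16 at day 21 and -2.13 at day 24. The other 10 probes were higher in that mean, with medians of 0.59, 0.63, 0.64 and 1.11 on those days, although 3 of the 10 lay below day 3 at day 12 and 1 on each later day. In grazed pieces, which took no part in choosing these probes, 36 of the 38 lay below day 3 in the mean of the later days (median -0.9) and 6 of the 10 lay above it. These tallies count some transcripts more than once if consecutive numbers form pairs, since 22 of the 36 called probes with a kept partner had a called partner. All control arrays of day 3 were scanned on a day of their own among the controls, and with scan day as a fixed block limma called 7 probes, 0 of them among the 48. The median difference of the 38 probes between the later days and day 3 was -2.08 in the controls without this block and -1.25 with it. The value with the block links the control days through the grazed arrays of day 3, 2 on scan day 1 and 3 on scan day 2. It is therefore not a comparison among controls alone, nor separate from the grazed arrays. Within the scan day that held 3 grazed arrays of day 3 and 3 of day 12, 34 of the 38 probes were lower at day 12, with a median difference of -0.48.

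**Figure D3:**
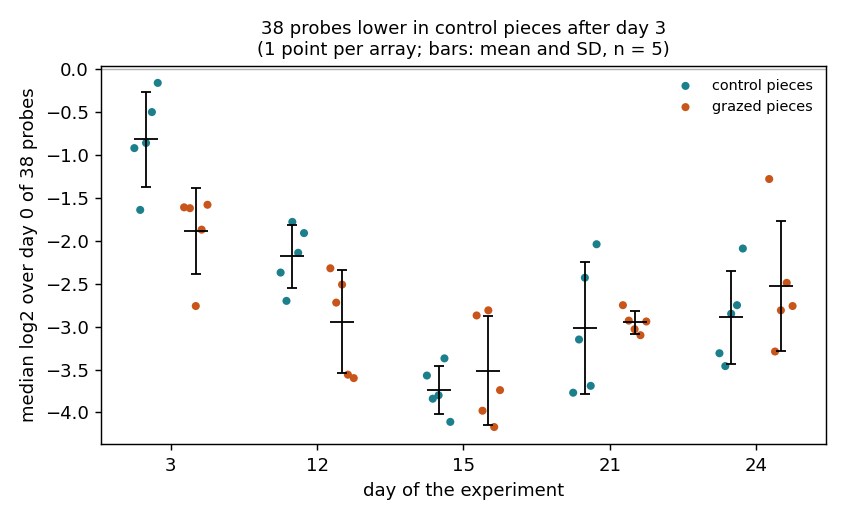
Median log2 ratio to the day 0 reference of the 38 probes lower in control pieces after day 3 (y axis) by day of the experiment (x axis), with 1 point per array, control pieces in teal and grazed pieces in orange, and black bars for the mean and SD of 5 arrays. The probes were selected on the control arrays, and in grazed pieces 36 of the 38 probes lay below their own day 3 level in the mean of the later days.

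Both arms were also set against the day 0 pool. In control pieces 15733 probes differed from the pool, 7737 higher and 7996 lower, and in grazed pieces 15606 did, 7516 higher and 8090 lower (limma, adjusted p under 0.05). With median centring in place of loess, 31010 probes differed in control pieces, 12337 higher and 18673 lower, and 28947 in grazed pieces, 11217 higher and 17730 lower. Most of these differences were small: 165 probes in control pieces were over 2-fold higher and 502 over 2-fold lower, and in grazed pieces the numbers were 140 and 626. In both arms 11566 probes were called in the same direction and 12 in opposite directions, with 3320 expected from independent lists. The reference was always labelled with Cy5, so any dye bias enters both lists. The design text names 1 pool, while the labels name the reference by arm, and whether both arms had the same pool is not known. If they had, the pool's own deviation enters both lists too, and part of the overlap may come from it. With no change at all and 1 pool of 5 pieces for both arms that deviates by chance, 5 simulated data sets gave a median of 9092 called probes in control pieces (5095 to 17746), a range that holds the observed count. In grazed pieces they gave a median of 9544 (7588 to 12686), below the observed count from all arrays. Without the 7 arrays with over 89% of probes detected, grazed day 24 replicate 3 was the only grazed array of its day. No simulation was run for that omission, so it is not set against this range. The simulated data sets gave 5183 probes called in both arms in the same direction (2652 to 10608), below the observed 11566. Across probes, which are not independent replicates, the arms' differences from day 0 correlated with r of 0.9, within the simulated 0.65 to 0.91, and their covariance of 0.12 lay above the simulated 0.025 to 0.076.

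In the reference channel, limma called 0 probes between grazed and control arrays over the 5 days, with 4944 at an unadjusted p under 0.05. On single days it called 101 probes at day 3, 4272 at day 21 and 20 at day 24, and 0 at days 12 and 15 (4174 and 433 at an unadjusted p under 0.05).

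Of the probes in the authors' deposited table, which gives fold changes between grazed and control pieces, 421 were among the probes kept here. In the authors' deposited table, the number of probes marked down per day was lowest at day 24, at 293, and highest at day 15, at 368. All 24 probes called over the 5 days stood in the authors' deposited table, which was made from the same arrays and is therefore not independent evidence. The authors' deposited table gave CUST_42366_PI408257168 as down by 2.24-fold at day 3, 5.41-fold at day 12, 2.66-fold at day 15, 8.27-fold at day 21 and 3.43-fold at day 24. Across probes, the log2 folds of the authors' deposited table had correlations with the daily differences computed here of 0.81, 0.86, 0.77, 0.76 and 0.88 in the order of the days.

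**Figure D4:**
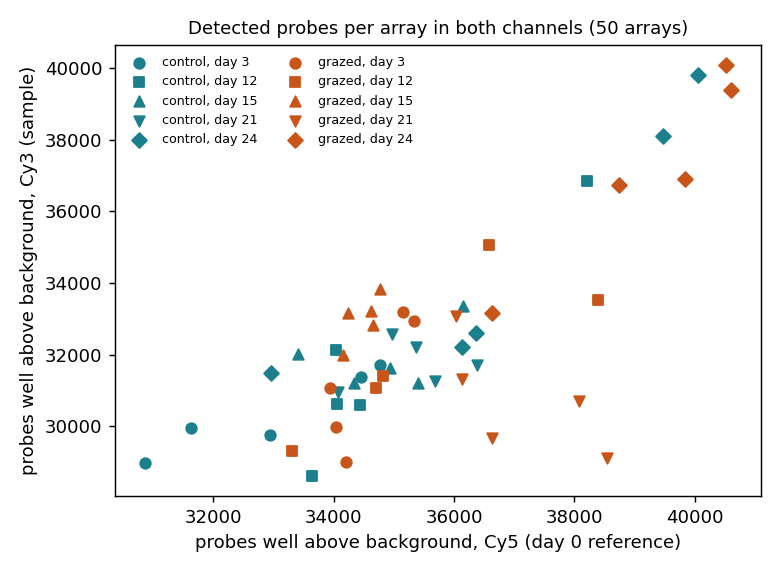
Number of probes well above background in the sample channel (Cy3, y axis) against the reference channel (Cy5, x axis) on each of the 50 arrays, with colour for the arm and marker shape for the day. The 6 arrays with the highest Cy5 counts, all above 38543, come from day 24.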

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

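The tests chosen only after the result was seen were those of the reference pools, the scan day and the pair partner for the probes called over the 5 days, of the slide or scan day and of days 21 and 24 only for the reference channel, and both tests of the arrays with many detected probes.

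Outlying arrays were looked for in 60 groups of 5 values with Dixon's test, of which chance gives about 1 in 20, and 4 were found. Control day 12 replicate 2 had 38215 probes above background in Cy5, the most of its group, beside 34434 on the next array. Grazed day 3 replicate 2 had a median correlation of log ratios with the other arrays of 0.34, the highest of its group, beside 0.24 on the next array. Grazed day 24 replicate 1 had a log2 ratio over day 0 of 1.84 for CUST_42366_PI408257168 and of 1.89 for CUST_42367_PI408257168, the highest of its group for both. These probes move as a pair and count as 1 observation. Without that array, limma called 45 probes over the 5 days in place of 24.

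The first pattern is the 24 probes called over the 5 days. Over 100 regroupings of the arrays within days, 1 gave as many probes, which is the real one, and the highest other count was 4. The regroupings argue against chance, but they ignored any pairs of same-numbered pieces, those of day 15 included. Simulated draws with other changed probes called a median of 2 and at most 363 unchanged ones, so the count of 24 is not firm evidence by itself. A difference between the reference pools is argued against by the median of 0.2% of the difference that stood in Cy5 (quartiles -3.7 and 4.8). With 1 array left out the median difference moved by at most 5.2%, and the count was 15 to 45. Probes called on these same arrays for differences large beside their SE could hardly move more, so the 5.2% decides nothing about a single array. With scan day as a block the median size was 111.4% of the full one (quartiles 104.9 and 115.4), while the median SE rose from 0.25 to 0.34. None of the 24 calls was kept. The larger SE, the fewer degrees of freedom and the changed ranking of all probes were not separated as reasons for the lost calls. No scan day held both arms of day 21. Its blocked estimate runs through grazed day 24 replicate 2, the only grazed array of day 24 on its scan day. These sizes therefore cannot exclude scan day as a source. Faults of single spots were argued against by 16 of 18 pair partners that differed the same way by at least 0.5 of the called probe's difference. Of these 18, 14 were called probes that were each other's partners, so those pairs were counted from both ends. Such faults stay open for the 2 others and for the 6 probes without a kept partner. In the check planned beforehand, uncalled neighbours had a median of 0.08 in the called direction, which met its limit for such faults. That check decides nothing, because most of these neighbours stand outside the pairs, where consecutive numbers hardly correlated (0.03). Grazing as designed stays open as a biological explanation that no independent data test.

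The second pattern is the reference channel, in which limma called 101 probes between grazed and control arrays at day 3, 4272 at day 21 and 20 at day 24, although the design text names 1 pool. Slide or scan day may account for day 21: control groups of different scan days differed in a median of 7013 probes in Cy5 (3116 to 11450), and those of days 15 and 21, scanned mainly on the same day, in 0 by limma (1050 at an unadjusted p under 0.05). The day 21 difference correlated at 0.04 with the arm difference of day 3 within slide 2 and at -0.23 with that of day 15 within slide 7. Each slide held 2 arrays of each arm. These values argue against different reference RNA on all days as the main source of the day 21 difference. They cannot exclude such RNA, since a batch effect at day 21 would hide it. Different RNA at days 21 and 24 only cannot be told apart from the batch, because the correlation of 0.51 within a slide rests on 1 grazed array. No biological explanation was tested, since the design gives none for the reference.

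The third pattern is the 7 arrays with over 89% of probes above background in Cy3, 6 of them from day 24. On 6 of the 7 the Cy5 count of the day 0 reference was also above that of each of the other 43 arrays (highest 38543), which argues against more transcripts in the sample RNA as the whole source and is in line with the hybridisation or scanning of these arrays as a candidate source. Omission of the 7 arrays left grazed day 24 replicate 3 as the only grazed array of day 24, so the probes called without them decide nothing. The day itself stays open as an untested biological explanation for the sample channel.

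On each day limma called 0 probes (1219 to 2268 at an unadjusted p under 0.05), and for grazing by day 0 (1235). Each of the 100 regroupings reaches a count of 0, so the regroupings decide nothing about chance for these counts. The highest other counts were 1178 at day 3, 3 at day 12, 457 at day 15, 26 at day 21 and 82 at day 24, and 476 for grazing by day. Regroupings that called as many as 1178, 457 and 476 probes may point to a structure of the arrays other than grazing, but whether they follow slide, scan day, replicate pairs or single arrays was not tested. For the control pieces over the days, 2 of 100 regroupings reached 48 probes, the real one included, which is under 1 in 20. The highest other called 819, which may point to such a structure too, and in simulated data up to 80 unchanged probes were called in a draw, so the count of 48 is not firm evidence of a change with the day.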

How the results depend on the processing

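Scan day as a block or alone, blocks of day and number, the omission of the 7 arrays with over 89% of probes detected and the first fit with bright spots were chosen after seeing the data. None of the named probes changed sign, but the balance of the 5-day calls did: 1 higher and 23 lower became 6 higher and 0 lower with scan day as a block, none of them among the 24, and 19 higher and 10 lower without the 7 arrays. The cause of the changes below was not tested, except that a strict filter tests fewer probes and that the first fit held diverged background parameters. Over the 5 days, the count of 24 was 58 with Agilent's log ratio (12 higher, 46 lower), 76 with median centring, 43 with scaling, 8 with a strict filter, 15 with slide as a random block, 6 with scan day as a block, 93 with array weights and 13 in the first fit with bright spots, all 13 among the 24. The correlation of same-numbered pieces was over 0.1 in every pair at day 15 only, but in 18 of 25 pairs in all, and 2, 3, 3, 4 and 3 of 5 correlated best with their own number in the order of the days, a hint from the data. The replicate block of day and number gave 167 probes (fixed) and 80 (random) over the 5 days, each with all 24 among them. The other 6 of 16 alternatives gave 17 to 29 probes, 20 of the 24 among them with the replicate number as a block across all days. Without the 7 arrays only 9 of 29 were among the 24. At day 3 the count of 0 was 5 with median centring and 54 with slide as a fixed block. At day 12 it was 269 with array weights. At day 15 it was 1 with the sample channel alone, 9 without background correction, 2 in the first fit, 1 and 18 with the replicate block of day and number (fixed, random), 57 with array weights, 4 in a separate fit, 1 within scan day 3 and 1 without the 7 arrays. At day 21 it was 573 with median centring, 55 with slide as a fixed block, 12 with scan day as a block and 3 in a separate fit. At day 24 it was 4712 with slide as a fixed block and 26 without the 7 arrays. Grazing by day gave 6 with scan day as a block and 17 without the 7 arrays. The count of 48 for control pieces over the days was 177 with Agilent's log ratio, 1846 with the sample channel alone, 74 without background correction, 84 with median centring, 16 with scaling, 10 with a strict filter, 29 with slide as a random block, 7 with scan day as a block, 96 with array weights and 73 without the 7 arrays. Against day 0, median centring gave 31010 probes in control pieces (12337 higher) and 28947 in grazed pieces (11217 higher), and without the 7 arrays grazed pieces gave 9697. The reference channel gave 32 without the 7 arrays. Slide as a fixed block could not be estimated for day 12, the 5 days, grazing by day and the control days, and the planned gene lists were not run.

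With 1 array left out, the 5-day count was 15 to 45. It was 15 without grazed day 3 replicates 1 and 3, grazed day 12 replicates 4 and 5, control day 15 replicates 3 and 4, grazed day 15 replicates 2 and 3, grazed day 21 replicates 4 and 5, control day 24 replicate 1 and grazed day 24 replicates 3 and 4, 38 without control day 3 replicate 2 and 45 without grazed day 24 replicate 1. Day 3 gave 0 to 7 (7 without control replicate 2, 1 without control replicate 4 or grazed replicate 1), days 12 and 21 gave 0 to 0, day 15 gave 0 to 6 (6 without grazed replicate 1, 3 without grazed replicate 3, 2 without control replicate 1) and day 24 gave 0 to 2 (2 without control replicate 4). Grazing by day gave 0 to 0. The control days gave 29 to 76 (29 and 30 without day 3 replicates 4 and 2, 31 without day 15 replicate 2 or day 24 replicate 1, 76 without day 12 replicate 2). Against day 0 the range was 14956 to 15631 in control and 14850 to 15527 in grazed pieces. The reference channel gave 0 to 3 (3 without control day 24 replicate 5, 1 without control day 21 replicate 5). CUST_42366_PI408257168 and CUST_42367_PI408257168 passed in all 50 omissions, and CUST_47029_PI408257168 in 29. Over the other alternatives the log2 difference was -2.278 to -1.726 for CUST_42366_PI408257168 and 0.5844 to 0.7995 for CUST_47029_PI408257168. CUST_42366_PI408257168 and CUST_42367_PI408257168 passed in 15 of 16, failing with scan day as a block (limma adjusted p 0.115 and 0.126), and CUST_47029_PI408257168 in 13, failing with slide as a random block (0.054), scan day as a block (1) and without the 7 arrays (0.0615). Median Cy3 signals of 3.2 to 21.3 times the local background limit dim probes.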

Other observations

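The tests of days 3, 12 and 21 as a group and of even-numbered pairs were chosen only after the result was seen. The daily differences between grazed and control pieces correlated across probes with r of 0.5 between days 3 and 12, 0.43 between days 3 and 21 and 0.6 between days 12 and 21, while the other pairs of days gave -0.19 to 0.17. Probes are not independent replicates, so arrays were regrouped within days. These 3 pairs were picked as the largest of 10, and the highest other correlations for them were 0.48, 0.35 and 0.49. With the best 3 of the 5 days picked anew in each regrouping, the lowest correlation among them was 0.43 in the real grouping and at most 0.35 in the others, so 1 of 100, the real one, was as large. All 5 grazed arrays of day 21 and some of days 3 and 12 were scanned on later days than their controls. The arms of day 15 were spread alike over scan days, and at day 24 only 1 grazed array was scanned apart. The regroupings break arm and scan day together, so they cannot separate grazing from scan day. Within single scan days the correlation between days 3 and 12 was 0.41, which argues against scan day as the whole source of that correlation. No scan day held both arms of day 21, so its correlations had no such check. A shared difference on those days may be a response to grazing, as a hypothesis, but limma's F test of grazing by day called 0 probes (1235 at an unadjusted p under 0.05), and days 15 and 24 did not take part.

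Probes with consecutive numbers moved together: their log ratios over the 50 arrays correlated with a median r of 0.45 over 27181 pairs, 0.45 above random pairs. These correlations include differences between days and arms. The correlation was 0.95 where the even number came first and 0.03 where the odd number did, a difference of 0.92, so an even number and the next may form a pair for 1 transcript, which the files do not state. With such pairs averaged, limma called 10 of 14081 pairs over the 5 days, all lower in grazed pieces, and 0 on each single day (608, 516, 501, 751 and 412 pairs at an unadjusted p under 0.05). In 1 of the 10, that of CUST_38979_PI408257168, the probes did not move together (r of -0.07). The log2 differences were -1.33 for that probe and -0.07 for its partner, so this call rests on 1 probe. Of the 24 called probes, 14 had a called partner.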
